A study of Arabidopsis thaliana with 12 samples.

How the data were processed

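The measurement was RNA abundance on Agilent single-colour arrays in 12 samples of Arabidopsis seedlings, with 3 arrays for each of 4 groups (wild type or labelled nlp67, sufficient or deficient potassium). Groups were taken from the sample titles, which differ from the treatment text as the report says. Per the labels, RNA was extracted with a Promega kit and labelled with Cy3 by Agilent's low input method from 0.2 µg of RNA. Per the file headers, the intensity values of each array were made by Agilent Feature Extraction 9.1 with background subtraction, spatial detrending and multiplicative detrending within the array, and none of these steps scales one array to another. The deposited value table holds intensity, equal to the median pixel signal of the spot in the scanner file for 99.934% of its 542640 cells, on a linear scale without background subtraction. What made the remaining 357 cells differ is not stated, and neither is any centring or scaling of that table. Its column medians were 501.75, 317.5 and 372.75 for the wild type at sufficient potassium, 487.0, 249.25 and 232.5 for arrays labelled nlp67 at sufficient potassium, 434.0, 313.0 and 331.5 for the wild type at deficient potassium and 440.25, 312.0 and 288.0 for arrays labelled nlp67 at deficient potassium. The direction of every difference follows from intensity, where a higher value means more signal.

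The report uses the processed signal of the scanner files, taken to log2 and scaled by subtracting the 75th percentile of each array. Control spots were left out, as were spots marked as outliers (0 to 114 per array), and spots of the same probe were averaged. Per the file headers, a spot not above background carries a surrogate value, and 9.59% to 15.71% of spots per array do, so levels far below background give no exact size. A difference was therefore given as a bound, at least so many fold, where a gene was well above background on all arrays of one group and on none of the other. The bound sets the brighter group against the lowest level read as well above background on each array of the dimmer group, or the measured level where that is higher. Sizes of other list members can rest in part on arrays where they were not well above background. A probe was tested where it was well above background on all 3 arrays of at least 1 group, which kept 32703 of 43603 probes. The files name probes by accession, locus or symbol. Names came from the TAIR10.1 annotation, through which 36163 probes matched by accession, 573 by locus and 444 by symbol, 37180 in all at 26755 loci. The other 6423 probes were left out of the gene counts, 2624 of them past the background rule, and were added as names of their own in one alternative. Each gene was represented by its brightest tested probe, which gave 21252 genes. Of 6689 genes with several probes, 44, 281, 57 and 0 had probes past the threshold in both directions on slides 2 and 3, for the responses of the wild type and of arrays labelled nlp67 and the genotype differences at sufficient and deficient potassium.

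Differences were tested with limma (3.58.1, R 4.3.3) by its moderated test, two-sided, in a single fit of all 12 arrays with a mean per group, no block and 8 residual degrees of freedom. Adjustment was by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The 5 comparisons were the response to deficient potassium in either labelled genotype, the genotype difference at either supply, and the difference of the responses. All this, the 23 gene lists and the rule for naming genes were written before the data were examined. Of 382 list members, 372 were matched with their written symbol among the names of the locus, and 12 carried a symbol that the annotation gives to another locus. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 23 lists, and again with the correlation estimated per list. No list call over all slides or over slides 2 and 3, with or without the slide as a block, held with the estimated correlation. That version rests on few residual degrees of freedom (without the block 8 over all slides and 4 over slides 2 and 3) and may have little power. A call that ended with it is not upheld, but the list is not shown to be unshifted either. The lists cover the NLP family, potassium transport, primary nitrate response, nitrogen, phosphate, sulfur and iron starvation, jasmonate, ethylene, abscisic acid, salicylate, cytokinin and auxin, reactive oxygen enzymes, photosynthesis, root hair, root endodermis, senescence, cell division, heat shock, clock, flavonoid and glucosinolate genes. Names were drawn by rule: NLP6, NLP7 and HAK5 in every comparison, the 8 highest and 8 lowest changes (5 and 5 for the difference of responses) among genes past the threshold, above background on all arrays compared and with groups that do not overlap, up to 2 bounds per direction, and up to 4 members per list past the threshold, or else the 2 with the smallest p. Where over 40 genes came out, members were kept to lists called by camera and the 5 lists with most members past the threshold. From these the text names a part. QQS, SR30, VAR2 and the low oxygen genes given by name were picked after their values had been seen, as was the fit of slides 2 and 3.

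Replicate number, slide and scan coincide, so arrays of the same number share a slide as batch, and the pairing rests on that. Whether same-numbered arrays deviate together was tested as the correlation across genes of their deviations from the group means. The lowest correlation of any pair was 0.33 on slide 1, 0.11 on slide 2 and 0.14 on slide 3, all over 0.1. As deviations within a group sum to 0 and slide 1 lies apart, these values cannot tell whether slides 2 and 3 pair. In a test added later, the differences between slides 2 and 3 correlated between labelled genotypes at r = 0.463 at sufficient and 0.261 at deficient potassium, and between the supplies at -0.202 to -0.074, so arrays of these slides were not seen to deviate together across supplies. Values with the slide as a block stand beside a list call, or a gene over all slides, where they change it. Genes named on slides 2 and 3 carry no blocked p-value. Of the named-gene values, 338 gained a call on those slides against the fit of all slides, and 324 with the block added, so some of these calls end with the block. The fit of slides 2 and 3 used 8 arrays with 4 residual degrees of freedom. These slides were kept because their differences correlated, so the standard errors and adjusted p-values of that fit can be too small. Alternatives planned before the data were examined were normexp background correction with an offset of 50 and quantile normalization, quantile normalization, median scaling, no background rule, a rule over all arrays, the mean of a gene's probes, the slide as a block, a fit of only the arrays compared, trend and robust variance, array weights, the deposited value table, a fold change of at least 1 on the log2 scale and leaving out each array. Fits were also made for each of the other ways to part the arrays of a comparison into groups of equal size, and for 100 draws for the difference of responses. The procedure was tested on simulated data of 21154 genes for the wild-type response with 100 changed genes per size. It recovered 56% of changes of log2 1 and 78% of log2 2 with 15 false calls over all slides, and 79% and 93% with 10 false calls over slides 2 and 3. The simulated noise was independent for each gene and array, without a shift of slide 1 and without correlation between genes. These figures therefore need not hold for the real arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for reading, Fisher's exact test and plots, and data.table (version 1.17.8) in R for tables. Studies of the mutant alleles, growth data and other series were not used here.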

Results

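Gene expression was measured in seedlings of Arabidopsis thaliana, the thale cress, of the wild type Col-0 and of a line labelled nlp67. The series describes that line as a knockout of NLP6 and NLP7, a pair of transcription factors of the NIN-like protein family, of which NLP7 is a known regulator of the response to nitrate. Per the labels, seedlings were 9 days old and had grown with sufficient or with deficient potassium, an ion that roots take up through the channel AKT1 and the high-affinity carrier HAK5. The questions are which genes respond to potassium supply, and whether the response differs where NLP6 and NLP7 are missing. The labels are not of one mind. Sample titles name Col-0 and nlp67 but no tissue, and the series design names whole seedlings and the nlp6 nlp7 knockout. The treatment text of the samples speaks instead of root tissue and of a dof1.7 knockout. Here the titles were followed for the groups and the series design for the tissue, which stays open. Each combination of genotype and potassium supply was measured on 3 single-colour Agilent arrays, 12 arrays in all, and each of 3 slides carried 1 array of every group. Among 43803 spots that are not controls, 72.3% to 77.1% per array lay well above background and 0 were saturated. The 75th percentile of processed signal was 2267 to 2614 intensity units on slide 1 and 1025 to 1939 on slides 2 and 3. The number of arrays limits the precision of every value below. Each group sat at the same position on every slide, so position and group cannot be told apart. No label says that replicates came from separate cultures, and the p-values therefore measure only the spread between these arrays, which may be technical.

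The transcripts of the targeted genes were close to absent on the arrays labelled nlp67 of slides 2 and 3 and were at the wild-type level on the arrays labelled nlp67 of slide 1. NLP7 read 0.81 to 1.1 (log2 relative to the 75th percentile of the array) on the 6 arrays labelled wild type. On slides 2 and 3 it read -8.98 and -7.64 in the arrays labelled nlp67 at sufficient potassium and -8.76 and -9.18 at deficient potassium, and was not well above background on any of them. On slide 1 it read 1.22 and 1.16. NLP6 has 2 probes, which read 1.76 to 1.98 and 0.79 to 1.21 on arrays labelled wild type. On slides 2 and 3 they read -5.85 to -5.10 and -7.61 to -6.10 on arrays labelled nlp67. On slide 1 the arrays labelled nlp67 gave 2 and 1.03 at sufficient and 1.81 and 0.92 at deficient potassium. NLP6 and NLP7 therefore go against the label of the 2 arrays labelled nlp67 of slide 1, and every direction given below for the arrays labelled nlp67 rests on that label. Within slides 2 and 3 (n = 2 arrays per group) NLP7 was at least 197-fold lower at sufficient potassium (limma, adjusted p = 7.7e-04) and at least 269-fold lower at deficient potassium (adjusted p = 0.00169). NLP6 differed there by -7.23 ± 0.20 (log2 ± SE, limma, adjusted p = 1.9e-04) and -7.55 ± 0.20 (adjusted p = 2.5e-04). Over all 3 slides (n = 3) the differences of NLP6 were -4.81 ± 2.24 and -5.04 ± 2.24, with limma adjusted p of 0.58 and 1. Those of NLP7 had an adjusted p of 0.602 and 1 and are given no size, since 2 of the 3 arrays labelled nlp67 of each group were not well above background. The alleles are not given in the sources used here, so where the probes lie relative to the disrupted parts is unknown. The probes of both genes were low on the arrays labelled nlp67 of slides 2 and 3, so they do report the loss in that line. Their signal on slide 1 argues against the same disruption in the slide 1 arrays labelled nlp67. For a different allele on slide 1, a probe outside the disrupted part would check nothing.

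**Figure D1:**
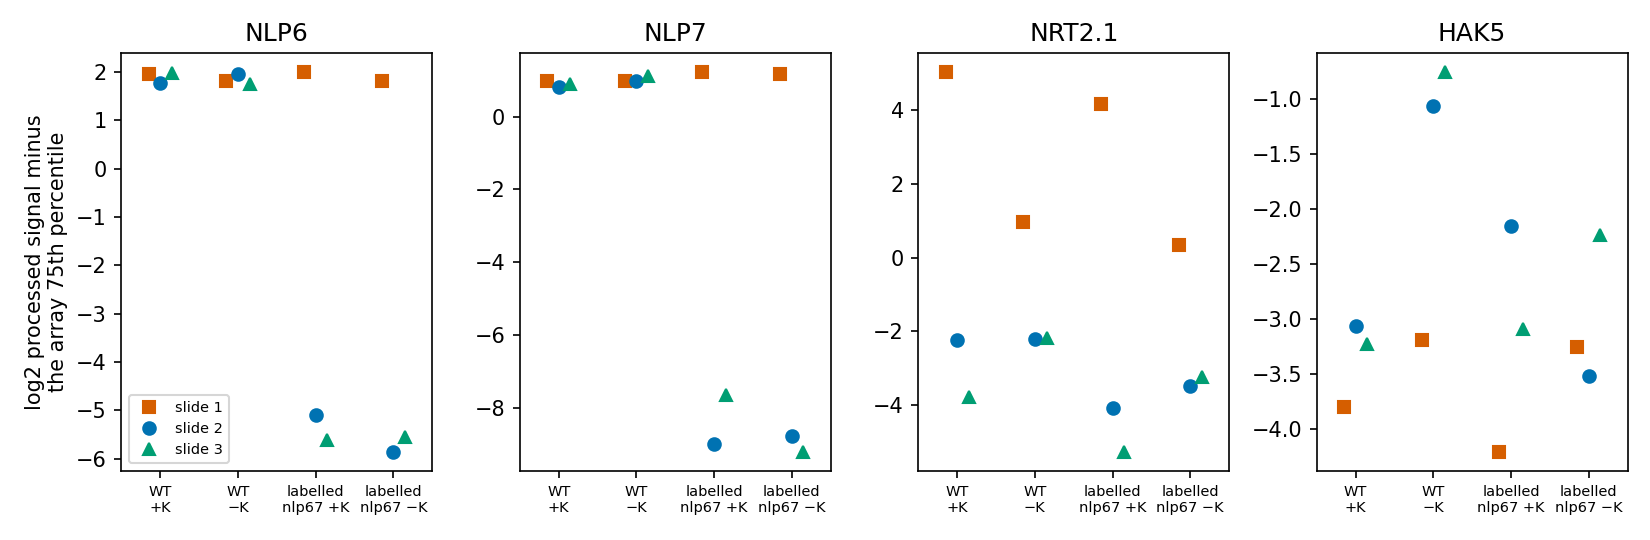
Level on each of the 12 arrays of NLP6, NLP7, the nitrate transporter NRT2.1 and the potassium carrier HAK5, as log2 processed signal minus the 75th percentile of the array, by labelled group, with 1 point per array and the slide as colour and shape. The slide 1 arrays labelled nlp67 lie at the wild-type level of NLP6 and NLP7 (NLP7 1.22 and 1.16), far above those of slides 2 and 3 (NLP7 -9.18 to -7.64).

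Slide 1 stood apart in other genes too. SR30, which codes for a splicing factor, read -4.32 and -4.44 on the slide 1 arrays labelled wild type and 2.39 to 2.77 on the other 10 arrays, by the brightest of its 3 probes. VAR2, which codes for a protease of the chloroplast thylakoid, read -1.05 and -0.97 on these arrays and 1.83 to 2.19 on the others. Both genes were picked after their values had been seen. Across genes, the differences between groups on slide 2 correlated with those on slide 3 at r = 0.715 to 0.829 over the 5 comparisons, and those on slide 1 with either at r = -0.117 to 0.224 (21161 to 21229 genes, which are not independent replicates). Each comparison is therefore given over all slides, as planned before the data were examined, and then over slides 2 and 3 alone. The latter fit has 2 arrays per group and was chosen after seeing the data. Slides 2 and 3 were kept because their differences correlated, which favours a small spread between their arrays. Standard errors and adjusted p-values over slides 2 and 3 can therefore be too small, and the numbers of genes and lists called there too high. Below, a value ± its error is a log2 difference ± the standard error of the limma fit, p-values are adjusted by Benjamini-Hochberg, and the 23 gene lists of this section were fixed before the data were examined.

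The first comparison asks what deficient potassium changed in the wild type. Over all slides the 8 highest rises measured on all 6 arrays included AT2G26695, which rose by 3.54 ± 0.53 (limma, adjusted p = 0.0286, n = 3), AT5G43570 by 3.29 ± 0.61 (0.0415), the cytochrome P450 gene CYP71B3 by 3.1 ± 0.55 (0.0371) and CBSX5 by 2.4 ± 0.49 (0.0484). Among the falls were UMAMIT31, of a family of amino acid transporters, at -1.33 ± 0.17 (0.0228), AT5G45210 at -1.31 ± 0.12 (0.00413), the sulfotransferase gene ST4A at -1.46 ± 0.22 (0.0294) and the glycerol-3-phosphate acyltransferase gene GPAT2 at -1.28 ± 0.26 (0.0472). The sulfate transporter gene SULTR3;1 was at least 4.04-fold higher (0.0441), and AT1G44010 at least 5.46-fold lower (0.0294), since neither was well above background in the dimmer group. In total 54 genes rose and 238 fell of 21252 tested, and limma gave 4633 at an unadjusted p under 0.05. Among those past the threshold with a log2 change of at least 1, 27 rose and 34 fell. All 292 also changed in the same direction on slides 2 and 3, which is no separate support, since those slides supply most arrays of the fit that called them. With the slide as a block 1440 genes changed, 406 up and 1034 down. Among them were AKT2 (limma, adjusted p = 0.0472, against 0.0764 without), MYB28 (0.0337 against 0.0702) and CYP79F2 (0.0448 against 0.0673). In the fit without the block AKT2 differed by 1.74 ± 0.44. In a limma fit of the 6 wild-type arrays alone 0 genes passed. Leaving out the slide 1 array at sufficient potassium gave 849 genes, and that at deficient potassium 2434, while leaving out any one wild-type array of slides 2 and 3 gave 3 or 4.

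Within slides 2 and 3 the potassium genes with the widest shifts were CIPK9, a kinase known from low potassium, at 3.25 ± 0.15 (limma, adjusted p = 1.4e-04, n = 2), CHX17, a cation exchanger, at 2.41 ± 0.19 (5.5e-04), AKT2, a channel of the phloem, at 2.34 ± 0.20 (7.0e-04) and HAK5 at 2.25 ± 0.47 (0.0108). Over all slides HAK5 differed by 1.7 ± 0.68 (0.19, and 0.067 with the slide as a block), with 0.61, 2.01 and 2.48 on slides 1, 2 and 3. ASN1, an asparagine synthetase known from darkness and sugar starvation, rose by 6.62 ± 0.42 (3.5e-04), the vegetative storage protein genes VSP2 and VSP1 by 6.27 ± 0.84 and 5.76 ± 0.83, the light-harvesting gene LHCB2.3 by 4.94 ± 0.14 and the dark-inducible gene DIN11 by 5.30 ± 0.59. The size for ASN1 rests in part on an array where it was not well above background. VSP1 and VSP2 are close copies, so a probe of one can read both. HSP21, a chloroplast heat shock protein, was at least 58.9-fold higher. Among the falls were AT1G12805 at -6.81 ± 0.24 (1.1e-04), the desaturase gene FTM1 at -5.73 ± 0.20, AT4G33560 at -5.34 ± 0.21 and ARD3, an enzyme of methionine recycling, at -4.57 ± 0.37 (5.9e-04), and the sulfate transporter gene SULTR1;3 was at least 15-fold lower. On these slides 4384 genes rose and 6057 fell, and 1275 and 712 of all genes changed by 2-fold or more.

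Several gene lists were called in the wild type. Over all slides limma's camera with a preset correlation of 0.01 put heat shock genes up (adjusted p = 6.2e-06), aliphatic glucosinolate synthesis down (4.1e-04), senescence up (0.00323), jasmonate up (0.00945) and sulfur starvation up (0.0498, and 0.0727 with the slide as a block). None of these calls held with an estimated correlation (adjusted p = 0.827, 0.827, 0.242, 0.827 and 0.827 with an estimated correlation). By limma 0 members of any list passed over all genes, and adjusted over the list alone 9 of 9 heat shock genes rose and 6 of 9 glucosinolate genes fell. The heat shock median was 0.00, 2.26 and 2.61 on slides 1, 2 and 3, and the glucosinolate median -0.53, -1.23 and -1.26. Within slides 2 and 3 all 9 heat shock genes rose and all 9 glucosinolate genes fell, over all genes and adjusted over the list alone alike (adjusted p = 1.3e-04 and 1.6e-04, and 0.489 and 0.385 with an estimated correlation). HSP17.4 rose by 6.01 ± 0.97, a size that rests in part on an array where it was not well above background. The heat shock and clock lists were chosen beforehand as signs of handling and harvest time. Whether either differed between groups was not tested, so shifts of these lists need not come from potassium or genotype. CYP79F2 and CYP83A1, enzymes of glucosinolate synthesis, changed by -1.73 ± 0.11 and -1.63 ± 0.11, and their regulator MYB28 by -1.44 ± 0.15. Of 15 sulfur starvation genes 11 rose, LSU1 by 3.42 ± 0.13, and 0 fell in the limma fit (adjusted p = 3.2e-04, and 0.316 with an estimated correlation). Of 11 senescence genes 7 rose, among them the regulator NAP by 3.22 ± 0.22 and SEN1 by 3.25 ± 0.24 (adjusted p = 0.00102, and 0.316 with an estimated correlation). Of 19 jasmonate genes 7 rose (adjusted p = 0.00764, and 0.593 with an estimated correlation). The numbers adjusted over the list alone were the same for these 3 lists.

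Other lists of the wild-type response held genes of both directions. Of 30 potassium transport genes in the limma fit 6 rose and 10 fell on slides 2 and 3, the same numbers adjusted over the list alone, and camera gave no shift (adjusted p = 0.91), with a median of -0.13 and a downward test beside a mean of 0.26 (over all slides -0.11 and 0.18, test up, 0.903). Of 34 primary nitrate response genes 4 rose and 15 fell (6 and 15 adjusted over the list alone; camera adjusted p = 0.188). Camera also called ethylene genes down, with 7 of 13 lower including the receptor ETR2 at -3.09 ± 0.15 (0.0275, and 0.419 with an estimated correlation). It called up reactive oxygen enzymes with 8 of 15 higher (0.0275), cytokinin genes with 7 of 13 higher (0.0275), abscisic acid genes with 7 of 15 higher including the phosphatase HAI1 at 2.74 ± 0.07 (0.0204) and clock genes with 6 of 13 higher (0.0202). With an estimated correlation the adjusted p of these 4 lists was 0.316, 0.59, 0.497 and 0.316. Adjusted over the list alone the numbers were 7, 9, 8, 7 and 6. The lists not called were nitrogen starvation (8 up, 5 down of 18), phosphate starvation (7 and 4 of 22), iron deficiency (3 and 2 of 17), root endodermis (5 and 2 of 14), salicylate (3 and 2 of 10), auxin (1 and 6 of 12), cell division (0 and 8 of 14), flavonoid (0 and 3 of 6), root hair (0 and 2 of 12), the NLP family (2 and 1 of 8) and photosynthesis (0 and 0 of 27), with limma camera adjusted p between 0.0947 and 0.683. The iron mean was -0.06 beside a median of 0.05 and the NLP family mean 0.25 beside a median of -0.02, and the photosynthesis test pointed up against a median of -0.06.

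**Figure D2:**
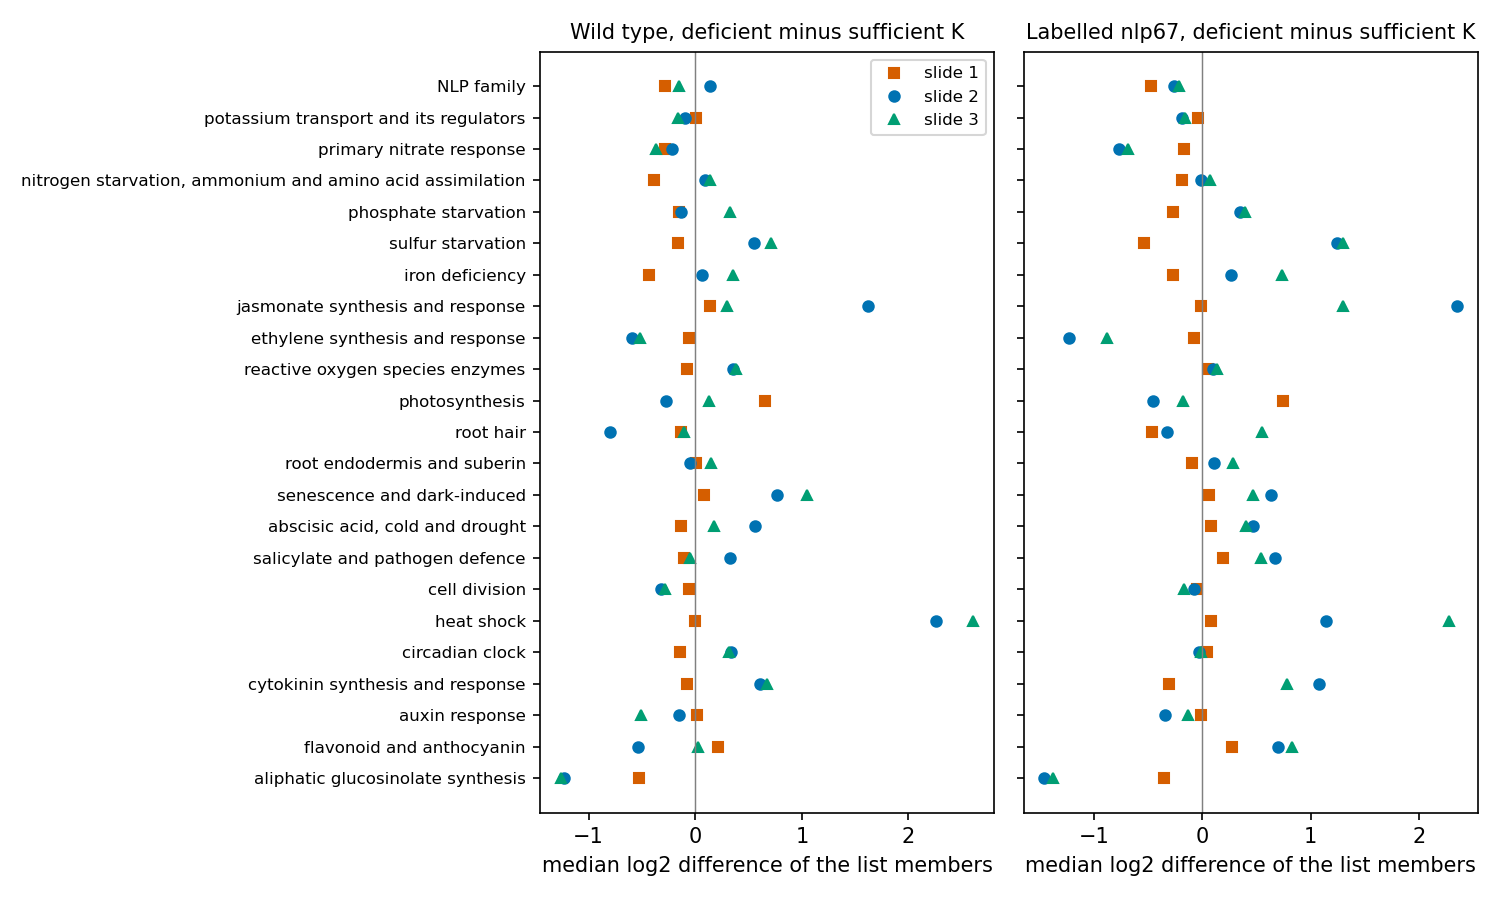
Median log2 difference between deficient and sufficient potassium of the tested members of each of 23 gene lists, 1 point per slide, for arrays labelled wild type (left) and nlp67 (right), with the lists on the vertical axis. Heat shock medians in the wild type are 0.00 on slide 1 against 2.26 and 2.61 on slides 2 and 3, and the glucosinolate medians are -0.53, -1.23 and -1.26.

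The arrays labelled nlp67 gave a response to deficient potassium of similar kind on slides 2 and 3. The galactinol synthase gene GolS4 rose by 6.39 ± 0.18 (limma, adjusted p = 7.7e-05, n = 2), the chloroplast amylase gene CT-BMY by 6.52 ± 0.70 (0.00138), AT3G05950 by 7.50 ± 0.85, VSP2 by 7.49 ± 0.84, CIPK9 by 3.43 ± 0.15 and AKT2 by 2.01 ± 0.20, and AT3G12900 was at least 61.2-fold higher. Among the falls were MYB27 at -5.05 ± 0.40 and FTM1 at -4.32 ± 0.20, and BEE3, a factor of brassinosteroid signalling, was at least 8.66-fold lower. HAK5 differed by -0.26 ± 0.47 (0.674), with -1.37 and 0.85 on slides 2 and 3. On these slides 3917 genes rose and 5821 fell, 1446 and 635 of all genes by 2-fold or more, and 3234 rose and 8073 fell with arrays scaled to the median instead. Across genes the responses of both labelled genotypes correlated at r = 0.706, with 2388 genes up and 3199 down in both, against 808 and 1659 for independent lists, and 462 of opposite direction. Over all slides 1 gene passed, AT5G03995 at -1.48 ± 0.14 (0.0215, n = 3), lower in each of the 3 slides (-1.04, -1.55 and -1.84), and limma gave 2860 at an unadjusted p under 0.05. Its adjusted p was 0.0742 with the slide as a block, and 0 genes passed there and in a fit of the 6 arrays alone. Without the slide 1 array at sufficient potassium 2254 genes passed, without that at deficient potassium 189, and without any one array labelled nlp67 of slides 2 and 3, 0.

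In the arrays labelled nlp67 of slides 2 and 3 camera called jasmonate, sulfur and abscisic acid genes up and nitrate genes down, calls that ended with an estimated correlation. Within slides 2 and 3, 12 of 19 jasmonate genes rose (13 adjusted over the list alone; camera adjusted p = 1.3e-05, and 0.32 with an estimated correlation). Of 15 sulfur starvation genes 12 rose and 1 fell (the same adjusted over the list alone; 8.1e-07, and 0.317 with an estimated correlation), with LSU1 at 3.65 ± 0.13 and the sulfate transporter SULTR2;1 at 2.54 ± 0.11. The cold- and drought-induced genes COR6.6, KIN1 and RD29A rose by 3.32 ± 0.09, 3.67 ± 0.21 and 2.86 ± 0.23, among 8 of 15 abscisic acid genes (2.6e-04, and 0.317 with an estimated correlation). Of 34 primary nitrate response genes 3 rose and 24 fell (4 and 26 adjusted over the list alone; 3.4e-04, and 0.317 with an estimated correlation), including the nitrate-inducible gene BT1 at -2.73 ± 0.32 and the nitrate reductase gene NIA1 at -2.05 ± 0.23. Heat shock rose with 8 of 9 genes (1.4e-04) and glucosinolate synthesis fell with 7 of 9 (3.4e-04), both 0.32 with an estimated correlation. Up as well were cytokinin with 8 of 13, salicylate with 4 of 10, iron deficiency with 8 of 17, senescence with 5 of 11, root endodermis with 6 of 14, phosphate starvation with 9 of 22 and flavonoids with 4 of 6, and down was ethylene with 9 of 13. Their camera adjusted p lay between 0.00262 and 0.044, and with an estimated correlation between 0.317 and 0.571. Not called were potassium transport (8 up, 11 down of 30; 0.861), photosynthesis (0 and 7 of 27; 0.156, 0.0454 with the slide as a block, and 0.802 with the block and an estimated correlation), reactive oxygen enzymes, clock, auxin, cell division, nitrogen starvation, root hair and NLP family genes. The potassium transport median and mean were -0.20 and 0.15 and those of auxin genes -0.24 and 0.11, with both tests down. Over all slides camera called jasmonate (1.3e-06), heat shock (1.1e-05), sulfur (1.1e-04), abscisic acid (1.7e-04), salicylate (0.00441), flavonoids (0.00682), cytokinin (0.0164), senescence (0.0314) and reactive oxygen enzymes (0.0364) up, and nitrate (2.4e-05), glucosinolate (2.4e-05) and ethylene (0.0314) down, all with an adjusted p of 0.278 with an estimated correlation. Both ethylene and reactive oxygen had an adjusted p of 0.0728 with the slide as a block. Adjusted over the list alone 10 nitrate genes fell over all slides. The slide 1 medians were -0.54 for sulfur, -0.01 for jasmonate and -0.17 for nitrate, against 1.24 and 1.3, 2.35 and 1.3, and -0.77 and -0.69 on slides 2 and 3.

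At sufficient potassium the lists called between labelled genotypes on slides 2 and 3 included photosynthesis, clock, flavonoid, salicylate and iron genes, and none of these calls held with an estimated correlation. Of 27 photosynthesis genes 18 were higher in the arrays labelled nlp67 and 0 lower in the limma fit (19 and 0 adjusted over the list alone; camera adjusted p = 4.7e-06, and 0.735 with an estimated correlation), among them the Rubisco gene RBCS1B by 1.36 ± 0.32 (limma, adjusted p = 0.0258, n = 2). Clock genes rose with 9 of 13 (2.2e-04, and 0.297 with an estimated correlation), PRR9 by 1.87 ± 0.29, in part from an array where it was not well above background. All 6 flavonoid genes fell (3.7e-04, and 0.654 with an estimated correlation), the chalcone isomerase gene TT5 at -1.52 ± 0.18. Salicylate genes fell with 6 of 10, including FMO1, an oxygenase of systemic resistance, at -2.13 ± 0.19 (0.00277, and 0.483 with an estimated correlation). Iron genes fell with 6 of 17, including the iron transporter IRT1 at -2.12 ± 0.39 and the reductase FRO2 at -2.16 ± 0.28 (0.00952, and 0.654 with an estimated correlation). Endodermis genes fell with 8 of 14 (0.00915) and cell division genes with 5 of 14 (0.00952), and glucosinolate genes rose with 5 of 9 (0.00329), with an adjusted p of 0.736, 0.654 and 0.654 with an estimated correlation. Of 34 nitrate genes 12 rose and 8 fell (12 and 10 adjusted over the list alone; 0.628). Of the 8 members of the NLP family 3 rose and 2 fell, NLP6 and NLP7 among the falls (0.628), with a median of 0.16, a mean of -1.44 and an upward test. NLP3 rose by 3.43 ± 0.12 (4.5e-04).

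Single genes with wide genotype differences at sufficient potassium on slides 2 and 3 included QQS, a regulator of starch content, at -5.88 ± 0.14 (limma, adjusted p = 1.3e-04, n = 2), which was 5.26 higher in the array labelled nlp67 on slide 1. Also lower were AT5G26200 at -4.05 ± 0.09, ARD3 at -3.98 ± 0.37 and SKOR, a potassium channel of xylem loading, at -2.34 ± 0.09 (5.5e-04). The sucrose exporter genes SWEET11 and SWEET12 rose by 3.76 ± 0.46 and 3.43 ± 0.25, the steroid dehydrogenase gene HSD1 was at least 16.5-fold higher, and AT3G12900 was at least 15.5-fold lower. HAK5 differed by 0.53 ± 0.47 (0.421). In all 3360 genes were higher and 3135 lower (3897 and 2562 with arrays scaled to the median). Over all slides 0 genes passed by limma, with or without the slide as a block, and 1902 had an unadjusted p under 0.05. Without the slide 1 array labelled nlp67 at sufficient potassium 792 genes passed, and without the wild-type array of slide 1, 33. Camera called flavonoids down (8.7e-04), salicylate down (0.00696), clock up (0.00696) and photosynthesis up (0.0101) over all slides, with an adjusted p of 0.68, 0.68, 0.692 and 0.975 with an estimated correlation. Adjusted over the list alone 1 flavonoid gene fell, and over all genes 0 members of any list passed. With the slide as a block iron (0.0296) and cell division (0.00131) were called down as well (0.997 and 0.854 with the block and an estimated correlation). The photosynthesis median was -0.55, 0.68 and 0.80 on slides 1, 2 and 3, and the flavonoid median 0.18, -1.10 and -1.04.

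At deficient potassium camera called nitrate response genes lower in the arrays labelled nlp67 of slides 2 and 3, a call that ended with an estimated correlation. Of 34 members 11 fell and 0 rose by limma (14 and 3 adjusted over the list alone; camera adjusted p = 5.4e-04, and 0.342 with an estimated correlation). The nitrate-inducible regulator HRS1 was at -2.67 ± 0.22 (limma, adjusted p = 0.00859, n = 2), BT2 at -2.59 ± 0.42, NIA1 at -2.39 ± 0.23 and BT1 at -2.04 ± 0.32. Sulfur starvation genes rose with 6 of 15 and fell with 1 (11 and 2 adjusted over the list alone; 4.0e-05, and 0.342 with an estimated correlation), GGCT2;1, an enzyme of glutathione breakdown, by 1.83 ± 0.14. Jasmonate genes were called up with 1 of 19 past the threshold (3 adjusted over the list alone), the synthesis gene AOC1 at 2.09 ± 0.37, photosynthesis with 2 of 27 (5 adjusted over the list alone), and glucosinolate synthesis with 2 of 9 (6 adjusted over the list alone), each at 7.0e-04, and 0.598, 0.791 and 0.396 with an estimated correlation. Heat shock was called down with 1 of 9, HSP18.2 at -1.78 ± 0.32 (6 adjusted over the list alone; 6.9e-04, and 0.57 with an estimated correlation). Salicylate with 2 of 10 lower (0.019), phosphate starvation with 5 of 22 (0.0329), senescence with 1 of 11 (0.0329) and potassium transport with 2 of 30 (0.034) were called down, with an adjusted p of 0.368, 0.396, 0.342 and 0.342 with an estimated correlation. Adjusted over the list alone 3, 7, 2 and 2 of their members were lower. Abscisic acid genes were called up only with the slide as a block (0.0305, against 0.0664 without, and 0.548 with the block and an estimated correlation). The NLP family had a median of 0.20 and a mean of -1.93, with NLP6 and NLP7 among its members. CYP712A1 was at least 53.7-fold lower, QQS was at -5.63 ± 0.14 (4.82 higher on slide 1) and AT5G19700 at -4.10 ± 0.40, and the jasmonate-regulated gene JRG21 rose by 4.05 ± 0.56 (0.0227). HAK5 differed by -1.97 ± 0.47 (0.07).

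In that comparison 545 genes were higher and 598 lower on slides 2 and 3 (399 and 368 with the slide as a block, n = 2). Over all slides 0 genes passed by limma, with or without the slide as a block, and 436 had an unadjusted p under 0.05. That is below the share of 0.05 of the 21252 tested genes that would lie there if none differed. Leaving out the slide 1 array labelled nlp67 gave 1 gene. Camera over all slides called nitrate down (0.00204), heat shock down (0.002), jasmonate up (0.00204), root hair up (0.0357), salicylate down (0.0357), senescence down (0.0487) and glucosinolate up (0.0487). With an estimated correlation their adjusted p was 0.767, 0.767, 0.931, 0.931, 0.609, 0.561 and 0.931, and over all genes 0 of their members passed, as adjusted over the list alone. The last 3 calls ended with the slide as a block (0.0682, 0.0662 and 0.0745), which called cell division down instead (0.00328, and 0.524 with an estimated correlation). Root hair genes, with medians of 0.75, 0.25 and -0.04 on slides 1, 2 and 3, were not called on slides 2 and 3 (0.449). The nitrate medians were -0.05, -0.23 and -0.20 and the sulfur medians -0.15, 0.91 and 0.63.

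The last comparison asks whether the response to potassium differed between the labelled genotypes. On slides 2 and 3 it did for NLP3, whose response was lower in the arrays labelled nlp67 at -2.65 ± 0.17 (limma, adjusted p = 0.00881, n = 2), SPL3, a factor of phase change, at -3.17 ± 0.23 (0.00881), SWEET12 at -3.24 ± 0.36 and CHX17 at -1.82 ± 0.27 (0.0155). It was higher for ARD3 at 4.44 ± 0.52 (0.0107), AT5G10040 at 3.77 ± 0.65, JRG21 at 3.31 ± 0.79, KIN1 at 2.48 ± 0.30, COR6.6 at 1.99 ± 0.13 and SKOR at 1.60 ± 0.13 (0.00881). HAK5 differed by -2.50 ± 0.67 (0.0537) and NLP6 by -0.32 ± 0.28 (0.463), and NLP7 is given no value, since it was not well above background in either group labelled nlp67. Of 34 nitrate genes the response of 10 was lower and of 1 higher (15 and 3 adjusted over the list alone; camera adjusted p = 4.3e-04, and 0.457 with an estimated correlation), BT1 at -2.40 ± 0.45 and HRS1 at -1.86 ± 0.32. Of 6 flavonoid genes 4 were higher (6 adjusted over the list alone; 0.00239, and 0.649 with an estimated correlation), TT5 at 1.43 ± 0.26. Of 13 clock genes 5 were lower (7 adjusted over the list alone; 0.00239, and 0.457 with an estimated correlation). Abscisic acid genes with 5 of 15 higher (0.0115), sulfur genes with 4 of 15 higher (0.01), root hair genes up and photosynthesis genes down with 0 members past the threshold by limma (both 0.0483) were called too, with an adjusted p of 0.649, 0.496, 0.668 and 0.685 with an estimated correlation. With the slide as a block iron and jasmonate genes were called up as well (both 0.0432, and 0.681 and 0.692 with an estimated correlation).

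For that difference of responses 1665 genes were higher and 1866 lower on slides 2 and 3 (1214 and 2482 with arrays scaled to the median). Over all slides 0 genes passed by limma, with or without the slide as a block, and 1139 had an unadjusted p under 0.05. That is close to the share of 0.05 of the 21252 tested genes that would lie there if none differed. Without the wild-type array of slide 1 at sufficient potassium 6 genes passed, and without that at deficient potassium 1. Camera over all slides called nitrate genes down and flavonoid genes up (both 0.00762, and 0.962 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. It called clock genes down only with the slide as a block (0.0468, against 0.0599 without, and 0.851 with the block and an estimated correlation). The nitrate medians were 0.00, -0.41 and -0.39 and the flavonoid medians 0.09, 1.14 and 0.80 on slides 1, 2 and 3.

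The deposited value table equals the median signal of the scanner files in all but 357 of 542640 cells. These cells lie on 95 probes of 79 genes, and 46 of the 95 probes belong to the gene lists used here, against 1.51% of all probes (odds ratio 65.8, Fisher's exact test, two-sided p = 5.3e-58). In the wild type at deficient potassium 118 of them were higher in the table and 10 lower, most of them higher on each of the 3 arrays. In the arrays labelled nlp67 at sufficient potassium these numbers were 3 and 58, with 56 of the 58 on the array of slide 1. In the wild type at sufficient potassium they were 56 and 27, with 10 and 24 on slide 1 and 29 and 2 and 17 and 1 on slides 2 and 3, and in the arrays labelled nlp67 at deficient potassium 23 and 62, most of them lower on each array. NLP7 read 89 in the table on both slide 1 arrays labelled nlp67, against 5785 at sufficient and 4932 at deficient potassium in the scanner files. HAK5 in the wild type rose by 3.90 on deficient potassium by the table (limma, adjusted p = 0.00718, n = 3) and differed by 1.38 by the scanner medians (0.23). NRT2.1, a high-affinity nitrate transporter with the close copy NRT2.2, differed between labelled genotypes at deficient potassium by -3.87 by the table (0.00137) and by -0.78 by the scanner medians. The results of the other paragraphs come from the scanner files, and fits of the table elsewhere are named as such.

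**Figure D3:**
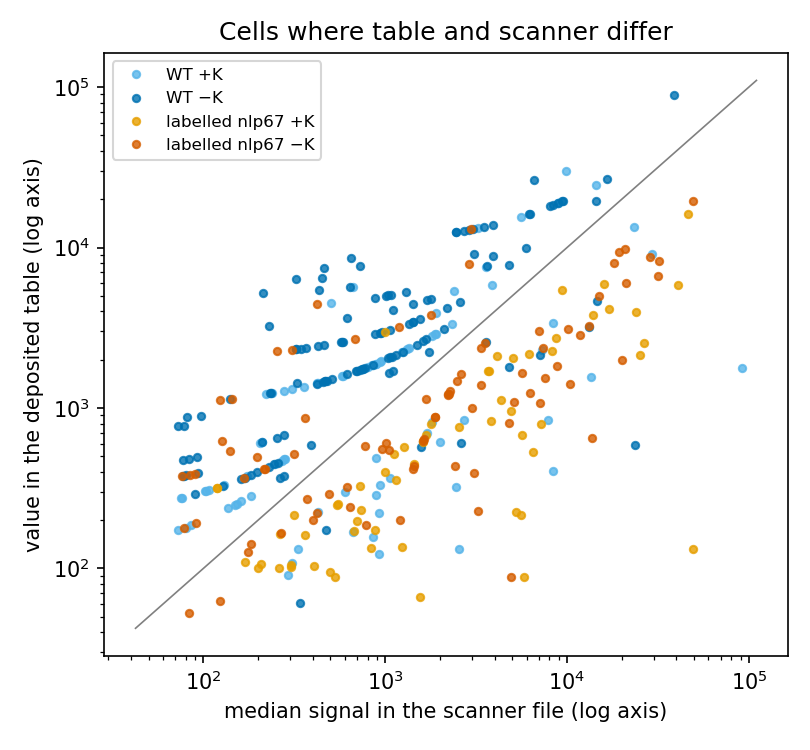
Value in the deposited table against the median signal of the same spot in the scanner file, both in intensity units on log axes, for the 357 cells where they differ, coloured by labelled group, with the line of equal values in grey. Points of the wild type at deficient potassium lie mostly above the line (118 of 128) and those of arrays labelled nlp67 at sufficient potassium mostly below it (58 of 61), of which 56 come from the slide 1 array alone.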

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

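Of the tests in this part, those on the slide 1 labels, on the value table cells and on signal and compression of slide 1 were chosen after the result was seen, whereas the predictions for the test of probe pairs and for the regroupings of arrays were written first.

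The difference of potassium responses between labelled genotypes was put here because 2 gene lists differed between the groups in a test of that difference. The primary nitrate response list had a median difference of -0.25 and the flavonoid and anthocyanin list one of 0.64 over all slides (limma's camera, adjusted p = 0.00762 for both, 0.00463 and 0.0279 with the slide as a block). Neither held with an estimated correlation (adjusted p = 0.962, and 0.851 with the block). By limma 0 single genes passed, with 1139 at an unadjusted p under 0.05, close to the share of 0.05 of all tested genes that would lie there if none differed. Random regroupings of the arrays gave up to 21 genes, and as the real number is 0, all 100 of 100 give at least as many by construction, which says nothing about chance.

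The arrays labelled nlp67 on slide 1 carried NLP6 and NLP7 at the wild-type level, and 3 technical readings were weighed. A swap with an array labelled wild type was argued against, since the lowest NLP7 level among those arrays was 0.81 and none lacked the transcript. A large share of mutant RNA mixed with wild-type RNA was argued against, since the lowest level was -0.68 standard deviations from the wild-type mean. A small share would lower the levels too little to be told from the spread of the wild-type arrays, and is not excluded. Plants with wild-type NLP6 and NLP7 under a mutant label remained open. Over 482 genes, the slide 1 difference was -2% of that on slides 2 and 3, with 47.8% of signs shared, as such plants could give. The wild-type potassium response of slide 1 also departed from that of slides 2 and 3 (slope 0.107 over 10441 called genes). A small difference could therefore arise whatever the genotype, and it does not decide this reading. The difference was read after the levels had been seen, so it is no independent test, and no biological explanation was tested.

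Cells of the deposited value table, in place of which the report uses the scanner files, were put here because 357 of 542640 differ from those files. Rounding was argued against by the smallest difference of 1.28-fold, and values of another array in a wrong column by 0 cells equal to the same spot elsewhere. Of the differing cells 95.2% kept the last 2 digits of the whole part, against 1.02% of unrelated pairs, which is in line with leading digits having been changed cell by cell. Whether this arose in export, editing or elsewhere was not tested, and no biological explanation was tested. Genes called with the table but not with the scanner medians numbered 84, 3, 3, 6 and 0 over the 5 comparisons, of which 22, 3, 3, 6 and 0 have a differing cell.

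Slide 1 lay apart from slides 2 and 3 in levels and in responses. Weaker signal was argued against by its lowest 75th percentile of 2266.7, above every array of the other slides. Compression of the responses was tested in the wild type, at r = 0.292 with slides 2 and 3 over 10441 called genes (slope 0.107). That r cannot decide it, since a strongly shrunken response with the noise of single arrays would also correlate weakly. Hybridisation or scanning effects on single probes were argued against as the sole cause. The slide 1 shifts of a pair of probes of the same gene correlated at r = 0.768 over 6655 genes, which are not independent replicates and whose probes may overlap. A shift that follows signal level could be shared by the probes of a gene and correlate as well. The correlation therefore does not decide on hybridisation or scanning in general. An earlier test of 10000 random lists, which put the nitrate list's slide 1 shift of 0.33 at percentile 100, pointed the same way and was set aside because random lists ignore co-regulation. Different plant material or growth on slide 1 could remain as well, and the data hold no label to test it.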

How the results depend on the processing

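The numbers of genes past the threshold depended on slide 1 more than on any normalization, and for every change given here the cause was not tested beyond the fewer arrays or genes that a setting names. The wild-type response gave 292 genes, and stayed within 1.5 times that under quantile normalization, the rule over all arrays, trend and robust variance, the deposited value table and added unmatched names. It gave 488 with normexp and quantile normalization, 163 with median scaling, 15 with no filter on dim probes, 167 with the mean of the probes of a gene, 112 with the scanner median signal, 61 with a log2 change of at least 1, and 0 with only the arrays compared (limma, where 4633 had an unadjusted p under 0.05 in the fit of all arrays). Leaving out 1 array gave 3 to 2434.

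With the slide as a replicate block the counts were 1440, 0, 0, 0 and 0 for the responses of the wild type and of the arrays labelled nlp67, the genotype difference at sufficient and at deficient potassium and the difference of responses. Apart from the blocked calls given in the report the block changed no other call of a list, and over all slides no other call of a named gene, except for KEA2, NYC1, GDH1, CHX17, ARD3, DIN11 and SQE6 in the wild type, which it added. Array weights, which ran from 0.0954 to 15 and whose estimate did not converge, gave 12468, 15041, 9744, 7533 and 8395. Slides 2 and 3 alone, chosen like the next 4 settings after seeing the data, gave 10441, 9738, 6495, 1143 and 3531. Counts from slides 2 and 3 can be too high, since these slides were kept because their differences correlated. Adding the replicate block there gave 10215, 9506, 6181, 767 and 3049, quantile normalization 10645, 9912, 6477, 1082 and 3427, and median scaling 10510, 11307, 6459, 1138 and 3696. Without both slide 1 arrays labelled nlp67 the counts were 1327, 2372, 1563, 18 and 2.

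The deposited value table gave 4 genes for the response of arrays labelled nlp67, against 1, and 3 and 6 for the genotype differences at sufficient and deficient potassium, against 0. Only the arrays compared gave 0 for the response of arrays labelled nlp67. Leaving out 1 array gave 0 to 2254 for that response, 0 to 792 and 0 to 1 for the genotype differences and 0 to 6 for the difference of responses. Over the 23 lists and 5 comparisons, 30 list calls were made. The number was 19 with no filter on dim probes, 46 with array weights, 49 on slides 2 and 3, 53 there with the replicate block, 52 with quantile normalization and 48 with median scaling there, and 0 with an estimated correlation on either set of slides, with or without the replicate block, of which only the estimate over all slides without the block was planned. Leaving out 1 array gave 25 to 40.

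NLP6 and NLP7 kept their direction in every setting that gave a value, which leaves out NLP7 under the rule over all arrays, where it drops out. Both passed the threshold with array weights, in the 4 fits of slides 2 and 3 and without both slide 1 arrays labelled nlp67, NLP7 also with the deposited value table, and neither in any other setting, with a single array left out included. NLP6 differed at sufficient potassium by -7.37 with array weights, -7.23 on slides 2 and 3 with and without the replicate block, -7.26 there with quantile normalization, -7.20 with median scaling and -7.26 without both slide 1 arrays labelled nlp67. At deficient potassium these values were -7.30, -7.55, -7.62, -7.58 and -7.54. The fitted values of NLP7, which are no measured sizes since it was not well above background on slides 2 and 3 in arrays labelled nlp67, were -8.58, -9.16, -9.34, -9.12 and -9.20 at sufficient and -10.09, -10.00, -10.10, -10.03 and -9.98 at deficient potassium, and -5.00 and -5.21 with the deposited value table, which rest on the cells of both slide 1 arrays labelled nlp67 that differ from the scanner files. Normexp with quantile normalization gave smaller values of -3.26 and -3.34 for NLP6 and -2.80 and -2.87 for NLP7, and the scanner median signal -3.51 and -3.79 for NLP6 and -2.99 and -3.28 for NLP7. Leaving out 1 array gave -7.26 to -3.45 and -7.54 to -3.71 for NLP6 and -9.20 to -4.10 and -9.98 to -4.81 for NLP7.

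Of the values of named genes under all settings, 7299 stayed on their side of the threshold, past it or not, 1922 gained a call, 180 lost theirs and 1 reversed. The reversed one was NRT2.4, a nitrate transporter gene, in the wild-type response, at 2.2 with the deposited value table (limma, adjusted p = 0.0165). By the scanner files it was lower without passing (0.208) and is given no size, since it was well above background on 1 of 3 arrays at deficient potassium. Where leaving out an array leaves 2 in a group, the fit pools the spread over groups. The share of tested genes rests on signal over background, which leaves dim genes without a size.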

Other observations

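The low oxygen list was written after other genes known from low oxygen, none of them on it, had been seen among the largest falls, and the slide 1 line differences were tested after SR30 had been seen; the predictions for the low oxygen list were written before its values were read.

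Genes known from low oxygen were lower at deficient potassium on slides 2 and 3, which no list fixed beforehand covers. A list of 15 further genes was added after FTM1, AT1G12805, AT5G10040, AT4G33560 and others had been seen, and since it was tested on the same arrays the pattern is a hypothesis. In the wild type 12 of 15 fell and 1 rose, with a median of -2.15 (limma's camera p = 3.9e-05, and 0.124 with an estimated correlation). ADH1, the alcohol dehydrogenase of fermentation, was at -4.30 ± 0.24 (limma, adjusted p = 2.5e-04, n = 2), the sucrose synthase gene SUS4 at -3.76 ± 0.17, the oxygen-sensing oxidase gene PCO1 at -3.61 ± 0.17 and the haemoglobin gene HB1 at -3.42 ± 0.15. In the arrays labelled nlp67, 8 fell and 1 rose, with a median of -0.67 (camera p = 0.0249, and 0.349 with an estimated correlation). There ADH1 was at -2.23 ± 0.24 and PCO1 at -3.36 ± 0.17, while the transcription factor gene HRE2 (-0.10 ± 0.17) and the decarboxylase gene PDC1 (-0.22 ± 0.15) did not pass. At sufficient potassium 9 of the 15 were lower in the arrays labelled nlp67 (median -0.90, camera p = 9.5e-06, and 0.105 with an estimated correlation), and at deficient potassium 0 changed by limma (median -0.07, camera p = 0.281). The difference of responses was 3.19 ± 0.24 for HRE2 and 2.07 ± 0.35 for ADH1, and 6 of 15 passed. On slide 1 the list median was -0.25 in both responses.

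On slide 1, 7 genes were higher and 3 lower by over 2 on the log2 scale in the array labelled nlp67 at both potassium supplies, of 21176 genes, and 2 passed that size with opposite signs. The genes below were picked by their values. SR30 read -4.32 and -4.44 on the arrays labelled wild type of slide 1 against 2.39 to 2.77 on the other 10 arrays, and its other probes -2.66 and -2.43 against 0.76 to 1.49 and -3.22 and -2.92 against -0.59 to 0.97. VAR2 read -1.05 and -0.97 against 1.83 to 2.19, and AT5G57130 read -1.37 and -1.54 against 0.54 to 1.18. QQS read -5.43 and -4.97 on the slide 1 arrays labelled wild type and -0.17 and -0.15 on those labelled nlp67. Slide 1 may hold a different pair of plant lines. Since the treatment text of the labels names a dof1.7 knockout and roots, both were tested for slide 1. A dof1.7 knockout was argued against by DOF1 (AT1G51700), taken here as DOF1.7, whose largest slide 1 difference was -0.83, though a probe outside the disrupted part would not show one. Root tissue on slide 1 alone, with seedlings on the others, was argued against by a slide 1 shift of -0.07 in the median of the photosynthesis list. The root lists ran toward it. Of 14 endodermis genes 7 were higher on slide 1 and 1 lower (median 0.37, limma's camera adjusted p = 0.0377, and 0.72 with an estimated correlation). Of 12 root hair genes 4 were higher and 1 lower (median 0.56, 0.107, and 0.815 with an estimated correlation). Root tissue on all slides would leave the photosynthesis shift near 0. The median signal percentile was 68.5 for photosynthesis genes (highest member 95.4), 78.2 for root endodermis genes (96.9) and 47.2 for root hair genes (75.1). Photosynthesis genes thus lay below root endodermis genes by both measures. These levels do not decide on root tissue, since no array of known tissue is at hand, and it stays open. Which lines slide 1 holds was not settled.

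A limma fit with a term for slide 1 put 4465 genes higher and 3803 lower on it, of 21252. All 14 cell division genes were higher (median 0.56, camera adjusted p = 5.7e-08, and 0.278 with an estimated correlation), 9 of 19 jasmonate genes were lower (median -1.11, 0.0128, and 0.72 with an estimated correlation), and 14 of 34 nitrate genes were higher and 4 lower (median 0.33, 0.0377, and 0.72 with an estimated correlation). The nitrate transporter gene NRT2.1 was 5.94 higher on slide 1. Camera also called up the NLP family, phosphate and sulfur starvation (adjusted p = 0.0384 each) and root endodermis genes (0.0377). It called down iron deficiency, abscisic acid, clock and auxin genes (0.0377 each). With an estimated correlation the adjusted p was 0.515 for the NLP family and 0.72 for the others.

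Parting the 6 arrays of each comparison into other groups of 3 gave 10 splits, too few for a share under 0.05. The real split gave 292 genes in the wild-type response and the highest other 0, so that 1 of 10 splits gave as many. For the response of arrays labelled nlp67 these were 1 and 0, and again 1 of 10 splits gave as many. For the genotype difference at sufficient potassium they were 0 and 28, and at deficient potassium 0 and 0. The 28 came from a split that keeps a pair of arrays of the same slide together, and the 4 splits that part all pairs, the real one included, gave 0 in both comparisons by limma, with 1902 and 436 at an unadjusted p under 0.05. The 436 lie below a share of 0.05 of all tested genes. Where the real number is 0, the 10 of 10 splits and the 100 of 100 draws for the difference of responses that gave as many are fixed beforehand and say nothing about chance.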
